A study of Homo sapiens with 10 samples.

How the data were processed

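RNA of PC3 cells, a human prostate cancer line derived from a bone metastasis, was sequenced in 10 libraries. In 5 libraries the cells had been cocultivated for 3 days with human bone marrow adipocytes, and in the other 5 they had not. Per the labels, every library carries a batch number from 1 to 5, and each number is held by 1 cocultivated and 1 non-cocultivated library. Libraries are named here by group and batch number. Per the labels' protocols, RNA was extracted on columns, libraries were made from 500 ng of RNA with an RNA quality number of 10 by a stranded, ligation-based mRNA kit, and they were sequenced on a NextSeq550 flow cell of 150 cycles. The labels do not say whether the libraries of a group come from separate cultures, so the replicate error given here covers at least the variation between libraries.

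Each deposited table lists the genes of 1 library with their length, effective length, expected count, TPM and FPKM values, per the file headers. The expected count is the number of reads that RSEM assigned to a gene, with reads that fit several genes shared out by likelihood, and the columns of the deposited tables are those of RSEM gene tables per the file headers. The deposited TPM values, per the file headers, give each transcript's share of the library after correction for effective length. The submitters' processing notes name bcl2fastq, Bowtie2 2.4.4 and RSEM 1.3.3. The genome build, the annotation release and the strand setting are not given in the sources used here, so no coordinates are given, and genes that overlap on opposite strands could not be separated here. The tables hold 60558 genes with Ensembl identifiers and symbols, and 83.8% of the expected counts were whole numbers within 0.005. Of the identifiers, 96.6% also occur in GENCODE v29, which was used only for Y linkage, GC content and transcript sequences.

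Library depth was 39074949 to 51515712 expected counts, and 23195 to 24939 genes had at least 1 count. A count of 0 allows up to 3 counts, which is 0.0583 to 0.0768 CPM of the library total depending on the library. Such limits cover counting error only, because reads amplified without molecular identifiers are not independent molecules. The 10 most abundant genes took 4.68% to 6.13% of the counts, and mitochondrially encoded genes took 1.25% to 3.23%. No pair of libraries of a group was a duplicate: between 2 libraries of a group, the chi-square per degree of freedom over genes was 4.93 to 53.5.

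Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passed filterByExpr on the group (minimum count 10, minimum total 15), which left 15690. Libraries were scaled by TMM, with factors of 0.953 to 1.04. The cocultivated group was compared with the non-cocultivated group by edgeR's quasi-likelihood F test (QL), with Benjamini-Hochberg (BH) adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Fold changes are cocultivated over non-cocultivated on the log2 scale, and their SE is the absolute log2 fold change divided by the square root of F. Levels of single genes are mean CPM on TMM-scaled library sizes with the SD over 5 libraries, while the floors and the sums of cell type markers are CPM of the library total, so the levels of markers do not add up exactly to their sum. The tests of the report, their samples, its gene lists and cell type markers and the rule for the named genes were fixed before the data were examined. The closing part names the tests chosen later, and its 3 lists of aryl hydrocarbon receptor, immediate early and p53 genes were written after the gene calls had been seen.

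The named genes were ANGPTL4, which the series title names, and the 10 highest and 10 lowest log2 fold changes among eligible genes. Those had an adjusted p under 0.05, a mean of at least 1 CPM and the same direction in all 5 batches. Clone-based symbols, Y-linked genes, XIST and TSIX were left out, while no filter on pseudogenes was run. To the named genes were added the 2 members of each gene list with the smallest p. The 3 members of each cell type list with the highest mean in the cocultivated libraries were added too. Some of these genes are not reported here. Lists with at least 5 tested members were compared with all other genes by limma's camera on log2 CPM (prior count 2, preset correlation between genes of 0.01), with BH adjustment over the 32 lists tested. Members higher or lower are counted at an adjusted p over all genes tested, and again with the adjustment over the list alone. For each of the 4 cell type lists, the summed CPM were compared by an exact two-sided permutation test of the group means, BH adjusted over the 4 lists. The smallest p it can give is 0.00794.

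The batch numbers pair the libraries, because the labels give them as a shared batch. For the deviations from the group means, the correlation across genes between the libraries of a batch was 0.329, -0.019, 0.073, 0.104 and 0.281 for batches 1 to 5, with a mean of 0.154. That mean had an exact one-sided permutation p of 0.0167 among the 120 possible pairings. Of the 5 non-cocultivated libraries, 2 (batches 1 and 5) correlated best with the cocultivated library of their own batch. No model is stated in the labels, so the fit without the batch was taken as the main one, and the fit with the batch as a block was an alternative.

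The alternatives fixed beforehand were the batch as a block, alone and with an offset for gene length, DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library totals, no filter on low counts, a stricter filter (1 CPM in 5 libraries), an absolute log2 fold change of at least 1, an adjusted p under 0.01, log2 TPM with a pseudocount of 1, and leaving out each library or each batch. For lists they were camera with a correlation estimated per list, fry, camera on voom values, and lists without members shared between lists. The block with a GC offset, the libraries without batches 1 and 5, the adipocyte markers without FABP4, and the other cell type sums without the marker that changed most were added after seeing the data.

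The fits were tested on simulated data, with counts for 15690 genes drawn from the real means and library sizes and 200 genes changed. The changed genes were drawn from those with a mean of at least 1 CPM, and no batch difference was simulated. The rates that follow thus do not cover genes of lower level or a change as broad as the real one. For the comparison of cocultivated with non-cocultivated libraries, edgeR recovered 88.1% of the genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, and 6.8% of its calls were false. DESeq2 recovered 92.5%, 100% and 100%, and 16% of its calls were false. camera on 15503 simulated genes called the 1 list of 32 that was raised 1.5-fold, with the preset and with the estimated correlation, and no other list. These simulated genes vary independently, so this does not test camera on correlated genes, for which the other splits of the real libraries are given in the closing part. FPKM values were not used here.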

Results

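Gene expression was measured by stranded mRNA sequencing in PC3 cells, an androgen-independent prostate cancer line, after 3 days with human bone marrow adipocytes (cocultivated, n = 5 libraries) and without them (non-cocultivated, n = 5). Each library held 39074949 to 51515712 expected counts. The comparison asks which transcripts of the cancer cells differ in the presence of marrow adipocytes, and the series title singles out ANGPTL4. On the first principal component (48.8% of the variance) the cocultivated libraries lay between 18.2 and 40.1 and the non-cocultivated ones between -31.9 and -20.3. The second component (11.2%) set both libraries of batch 1 apart, at -20.2 and -29.3.

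**Figure D1:**
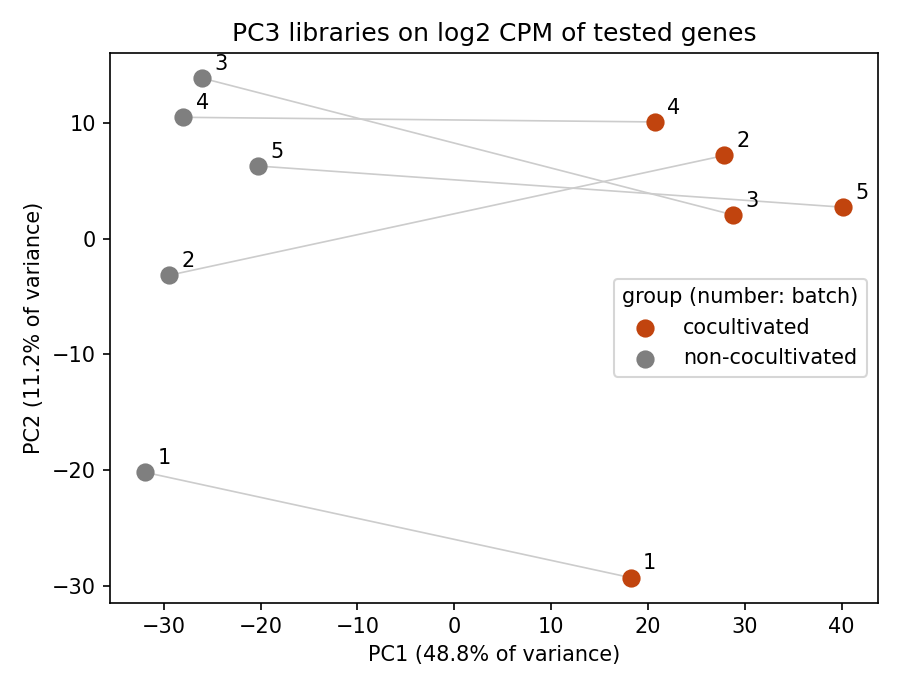
Principal components 1 and 2 of log2 CPM for the 10 libraries (axes: component scores with the percent of variance), points coloured by group and lines joining the libraries of a batch. The 5 cocultivated libraries lie between 18.2 and 40.1 on component 1 and the 5 non-cocultivated ones between -31.9 and -20.3.

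ANGPTL4 (ENSG00000167772), a secreted inhibitor of lipoprotein lipase, had the highest log2 fold change of the named genes, 6.40 ± 0.25 (SE, n = 5 and 5). Its level rose from 2.35 ± 0.602 to 199 ± 66.4 CPM (mean ± SD), which is 84.5-fold, with an edgeR QL adjusted p of 4.97e-09. The lowest cocultivated library held 141.5 CPM and the highest non-cocultivated one 3.28 CPM. Single genes passed as higher among targets of the fatty acid receptors PPAR (15 of 23), amino acid stress genes (20 of 24), antioxidant genes (20 of 25) and inflammatory genes (13 of 21). They passed as lower among LXR targets (5 of 11), hypoxia genes (15 of 24), glycolytic enzymes (13 of 19) and DNA replication genes (24 of 32). In all, 2801 genes were higher and 2478 lower of the 15690 tested, 33.6% of them, at a BH adjusted p under 0.05 from edgeR QL. The change was at least 2-fold for 358 of the higher and 283 of the lower genes, and 2719 and 2400 had the same direction in all 5 batches. With library totals in place of TMM the split became 2216 higher and 3555 lower, so the balance of the directions depends on the scaling.

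Besides ANGPTL4, the 10 strongest increases held PDK4 (ENSG00000004799), a kinase that inhibits pyruvate dehydrogenase, which rose from 3.41 ± 0.680 to 63.1 ± 12.4 CPM (log2 fold change 4.20 ± 0.16, edgeR QL adjusted p 4.17e-09). The aldo-keto reductases AKR1C1 (ENSG00000187134) and AKR1C2 (ENSG00000151632), which reduce steroids and carbonyls, rose by 4.72 ± 0.37 and 4.08 ± 0.36 on the log2 scale. These close paralogs share sequence (39.5% of the 75-base windows of AKR1C2 occur in AKR1C1), so the level of AKR1C2 is uncertain. FAM83A, AADAC, the immediate early transcription factor EGR1, PHLDA3, the hyaluronan-binding protein TNFAIP6 and the hair keratin KRT83 rose by 3.74, 3.67, 3.46, 3.28, 3.12 and 3.05 on the log2 scale. KRT83 is uncertain too, because its increase of 6.61 CPM is less than the 10.2 CPM that the windows it shares with KRT81 and KRT86 could carry. The strongest decrease was that of the axonemal dynein DNAH8 (ENSG00000124721), from 2.219 ± 0.2597 to 0.1365 ± 0.1185 CPM (log2 fold change -3.97 ± 0.33). In cocultivated replicates 3 and 5 DNAH8 lay at 0.05194 and 0.02204 CPM, within the 3 counts that a count of 0 allows, so the size of its change is uncertain. The phosphatase regulator PHACTR3 (ENSG00000087495) dropped from 65.1 ± 6.28 to 4.82 ± 1.66 CPM (-3.75 ± 0.18). DNAH8 and PHACTR3 were followed by the collagenase MMP13 (-3.29 ± 0.23), MSMP (-3.24 ± 0.56) and the cytochrome P450 CYP1A1 (-3.21 ± 0.25). KCNJ6, FAM20A, REG4, the cholesterol exporter ABCG1 and the matrix protein SPARC had log2 fold changes of -3.00, -2.92, -2.85, -2.82 and -2.81. Among these 20 genes the largest edgeR QL adjusted p was 6.02e-04, for MSMP.

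**Figure D2:**
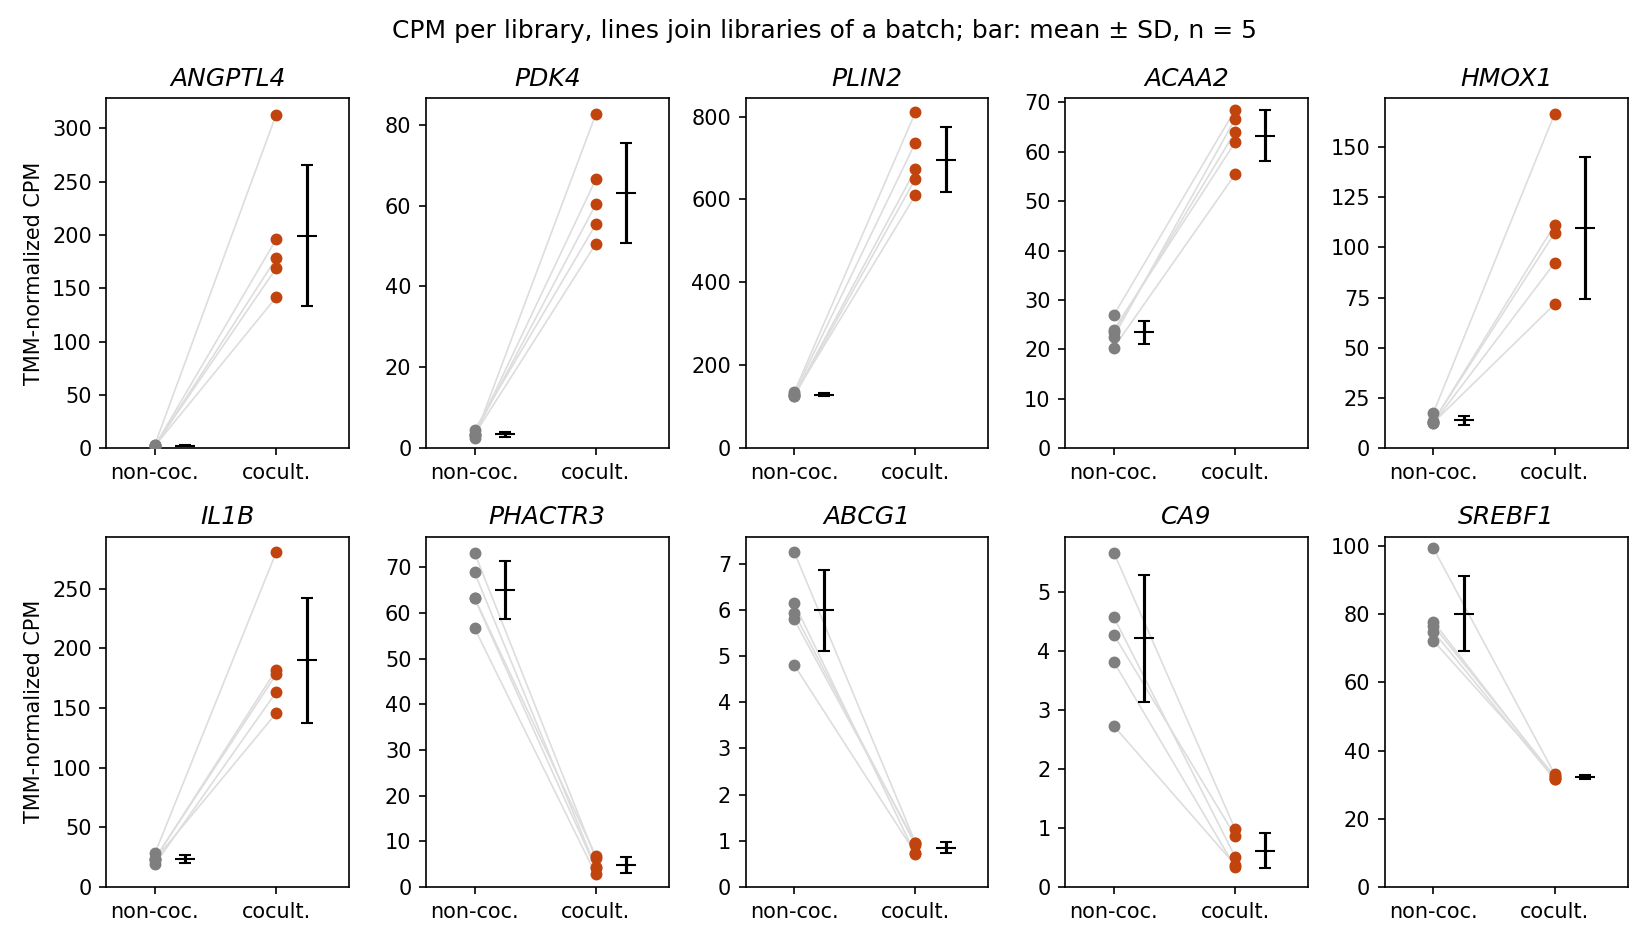
Level of 10 named genes in each library (vertical axes in CPM, one panel per gene), with lines joining the libraries of a batch and bars giving the mean ± SD of each group (n = 5). ANGPTL4, PDK4, PLIN2, ACAA2, HMOX1 and IL1B are higher in the cocultivated library of all 5 batches, and PHACTR3, ABCG1, CA9 and SREBF1 are lower in all 5.

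Of the 32 lists of genes tested with camera, 11 were higher and 5 lower after coculture. None of them was called when the correlation between genes was estimated for each list, where the smallest adjusted p was 0.196 and an unadjusted p under 0.05 was reached by 5 lists higher and 1 lower. In 99 other splits of the same libraries, camera with the preset correlation called up to 10 lists in a direction, with a median of 5 in the direction that had more. The split with 10 differed from the real one by the swap of 1 batch pair. Every other split keeps part of the coculture contrast, because the 5 libraries of a group cannot be shared evenly. The numbers of lists called in other splits are thus not rates of false calls. As many lists as the 5 lower ones were called, in either direction, in 51 of 100 splits. That share is raised because the smaller direction of the real split is set against the larger one of the others. The camera p of mitosis, DNA replication, lipid droplet, ER chaperone and hypoxia genes was matched or undercut in 67, 13, 9, 9 and 6 of 100 splits, and that of glycolysis and protease genes in 5. The calls of single genes inside each list do not rest on camera.

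Targets of PPAR, the receptors through which fatty acids induce genes of their own use, were higher as a list. Of 23 tested members 15 rose and 2 fell (16 and 2 adjusted over the list alone), with a camera adjusted p of 2.66e-07 and an adjusted p of 0.196 with an estimated correlation. The droplet coat protein PLIN2, PDK4 and ANGPTL4 had the smallest p of its members. The lipid droplet and triglyceride list had 9 members higher and 2 lower of 20 (10 and 2 adjusted over the list alone; camera adjusted p 0.00385, adjusted p 0.34 with an estimated correlation). PLIN2, a member of this list too, rose from 129 ± 3.87 to 696 ± 78.7 CPM (log2 fold change 2.43 ± 0.07, edgeR QL adjusted p 4.37e-10), and the monoglyceride lipase MGLL rose by 1.09 ± 0.09. For fatty acid oxidation, 9 of 25 members were higher and 2 lower, over the list alone as well (camera adjusted p 0.0168, adjusted p 0.23 with an estimated correlation). They include the thiolase ACAA2 (1.43 ± 0.07) and the mitochondrial carnitine carrier SLC25A20 (0.88 ± 0.06). With the batch as a block 10 were higher and 5 lower, and without members held by more than 1 list, this list was no longer called (camera adjusted p 0.689). For fatty acid uptake and activation, 8 of 16 were higher and 3 lower (8 and 5 adjusted over the list alone or with the batch as a block), with opposite changes of the lipoprotein receptor VLDLR (1.84 ± 0.12) and the transporter SLC27A2 (-0.99 ± 0.12), and the list was not called (camera adjusted p 0.253).

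Targets of LXR, the oxysterol receptor that drives cholesterol export, were lower: 5 of 11 fell and 0 rose, over the list alone as well (camera adjusted p 0.00113, adjusted p 0.196 with an estimated correlation). ABCG1 dropped from 5.99 ± 0.876 to 0.851 ± 0.123 CPM (edgeR QL adjusted p 2.26e-08). MYLIP, a ubiquitin ligase for the LDL receptor, had a log2 fold change of -2.08 ± 0.09. SREBF1, a transcription factor of lipid synthesis that is itself an LXR target, dropped from 80.2 ± 10.9 to 32.2 ± 0.622 CPM (-1.31 ± 0.08). In fatty acid synthesis and desaturation, 6 of 16 members fell and 1 rose, over the list alone as well, among them the malic enzyme ME1 (-0.35 ± 0.04), and camera did not call the list (adjusted p 0.108). In cholesterol synthesis and uptake, 3 of 25 rose and 0 fell (2 and 0 adjusted over the list alone, but 5 and 3 with the batch as a block), with NSDHL at 0.27 ± 0.07 (camera adjusted p 0.483). NSDHL was not called without batch 2 (edgeR QL adjusted p 0.0645). The cholesterol list was called as higher without non-cocultivated replicate 1 (camera adjusted p 0.036) and without batches 1 and 5 (0.0335), but with all libraries the adjusted p was 0.926 at an estimated correlation of 0.767.

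Hypoxia genes were lower: 15 of 24 fell and 4 rose (17 and 4 adjusted over the list alone; camera adjusted p 9.04e-05, adjusted p 0.325 with an estimated correlation). The carbonic anhydrase CA9 dropped from 4.21 ± 1.07 to 0.614 ± 0.292 CPM (log2 fold change -2.76 ± 0.27), and the vasodilator peptide ADM had a log2 fold change of -0.69 ± 0.04. Of 19 glycolysis genes 13 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p 1.76e-05, adjusted p 0.21 with an estimated correlation). PFKL and PGK1 both had log2 fold changes of -0.33, with SE of 0.04 and 0.05. Among 35 nuclear genes of the respiratory chain 5 fell and 1 rose (3 and 1 adjusted over the list alone, but 14 and 4 with the batch as a block; camera adjusted p 0.168), with NDUFV2 and SDHA at -0.21, and this list was called as lower without non-cocultivated replicate 1 (camera adjusted p 0.0365, but adjusted p 0.799 with an estimated correlation and all libraries). None of the 13 mitochondrially encoded genes was called by edgeR QL, over all genes or adjusted over the list alone, or by DESeq2 or limma-voom, and 0 had an unadjusted edgeR QL p under 0.05 (camera adjusted p 0.874 for the list). MT-ND4L (0.34 ± 0.26) and MT-ND4 (0.26 ± 0.25) took the opposite sign without batches 1 and 5, -0.24 and -0.28.

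The stress response lists were higher. For the ATF4 response to amino acid shortage, 20 of 24 members rose and 1 fell, over the list alone as well (camera adjusted p 8.56e-09, adjusted p 0.21 with an estimated correlation). Asparagine synthetase ASNS rose from 76.0 ± 3.10 to 181 ± 22.7 CPM, and SESN2, an inhibitor of growth signalling, rose by 1.58 ± 0.10 on the log2 scale. Of the 25 antioxidant targets of NRF2, 20 rose and 2 fell, over the list alone as well (camera adjusted p 5.81e-07, adjusted p 0.21 with an estimated correlation). Haem oxygenase HMOX1 rose from 13.9 ± 2.15 to 110 ± 35.3 CPM (log2 fold change 2.98 ± 0.20, edgeR QL adjusted p 2.18e-07), and AKR1C1 and AKR1C2 are members too. Among ER chaperones and genes of the unfolded protein response 13 of 20 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p 1.37e-05, adjusted p 0.248 with an estimated correlation). The chaperone HSPA5 rose from 999 ± 22.7 to 1704 ± 266 CPM and the transcription factor XBP1 by 0.63 ± 0.08 on the log2 scale. Of the metallothionein list 3 members were tested, too few for camera, and 1 was higher (2 adjusted over the list alone or with the batch as a block).

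Inflammatory genes of the NF-kB list were higher, with 13 of 21 up and 2 down, over the list alone as well (camera adjusted p 2.51e-05, adjusted p 0.196 with an estimated correlation). The cytokine IL1B rose from 23.3 ± 3.25 to 190 ± 52.6 CPM (log2 fold change 3.03 ± 0.17, edgeR QL adjusted p 5.11e-08), and the inhibitor NFKBIA rose by 0.58 ± 0.04. Of the glucocorticoid response list, which also holds ANGPTL4 and NFKBIA, 9 of 15 rose and 4 fell (10 and 4 adjusted over the list alone; camera adjusted p 0.00834, adjusted p 0.21 with an estimated correlation). ERRFI1, an inhibitor of the EGF receptor, rose by 0.84 ± 0.05. Angiogenesis factors had 10 higher and 3 lower of 18 (11 and 5 adjusted over the list alone; camera adjusted p 0.0156, adjusted p 0.196 with an estimated correlation), with the growth factor FGF1 at 1.93 ± 0.18. ANGPTL4 belongs to the angiogenesis list too and had the smallest p of its members. With the batch as a block the angiogenesis list was not called (camera adjusted p 0.0503). Without members of other lists, neither the angiogenesis list (camera adjusted p 0.23) nor the glucocorticoid list (0.0585) was called. Interferon-stimulated genes had 8 lower and 1 higher of 25, over the list alone as well (8 and 2 with the batch as a block), with IFIT2 at -0.70 ± 0.06 and IFIT3 at -0.56 ± 0.05. Camera did not call that list (adjusted p 0.0918, adjusted p 0.21 with an estimated correlation) except without non-cocultivated replicate 3 (0.0435). Antigen presentation had 4 higher and 1 lower of 13 (5 and 1 adjusted over the list alone, 8 and 1 with the batch as a block), with HLA-E at 0.40 ± 0.07 and the peptidase ERAP1 at 0.31 ± 0.06. Camera called it (adjusted p 0.0985 with all libraries, adjusted p 0.532 with an estimated correlation) only without non-cocultivated replicate 5 (0.0414), among the libraries left out, and ERAP1 was not called from TPM values (limma adjusted p 0.143).

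Genes of the mesenchymal transition list were higher in 9 and lower in 2 of 18 cases (9 and 3 adjusted over the list alone; camera adjusted p 0.00432, adjusted p 0.21 with an estimated correlation). Its member SPARC fell. The proteases and inhibitors of invasion also moved both ways, with 12 higher and 4 lower of 23 (13 and 4 adjusted over the list alone; camera adjusted p 0.0409, adjusted p 0.248 with an estimated correlation). The collagenases MMP13 and MMP1 (-1.16 ± 0.05) fell, and the urokinase PLAU rose from 1040 ± 82.8 to 2019 ± 79.2 CPM. The protease list was not called with the batch as a block (camera adjusted p 0.0503), without cocultivated replicate 3 (0.0641) or without members of other lists (0.104). Of 20 epithelial junction and keratin genes 10 fell and 6 rose, over the list alone as well (camera adjusted p 0.231), with KRT8 at -0.94 ± 0.06 and CLDN4 at 0.46 ± 0.04.

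DNA replication genes fell in 24 of 32 cases and rose in 1, over the list alone as well (camera adjusted p 7.08e-08, adjusted p 0.29 with an estimated correlation). Thymidylate synthase TYMS dropped from 91.5 ± 6.36 to 56.0 ± 5.57 CPM and the helicase subunit MCM7 had a log2 fold change of -0.44 ± 0.05. Of 28 mitosis genes 5 fell and 0 rose (1 and 0 adjusted over the list alone, but 14 and 0 with the batch as a block; camera adjusted p 0.00652, adjusted p 0.544 with an estimated correlation), with KIF20A at -0.39 ± 0.09 and the cyclin CCNA2 at -0.22 ± 0.06. CCNA2 was not called without batch 3 (edgeR QL adjusted p 0.0632).

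The signalling and tissue lists that camera did not call had members in both directions. In the TGF-beta list 5 of 18 were higher and 8 lower (8 and 8 adjusted over the list alone or with the batch as a block; camera adjusted p 0.874), with ID2 at -1.37 ± 0.06, and its median of 0.04 and mean of -0.01 differ in sign. Wnt targets had 4 higher and 4 lower of 10, over the list alone as well (camera adjusted p 0.686), with the stem cell receptor LGR5 at -2.28 ± 0.12 and APCDD1 at -1.80 ± 0.18. Their median of 0.12 and mean of -0.24 also differ in sign. FOXO targets had 3 higher and 6 lower of 15, over the list alone as well (camera adjusted p 0.236), with BCL6 at -0.67 ± 0.05 and GADD45A at 0.98 ± 0.10. Bone metastasis and bone matrix factors had 7 higher and 5 lower of 15 (8 and 5 adjusted over the list alone; camera adjusted p 0.235). The bone morphogenetic protein BMP6 rose from 28.8 ± 1.86 to 140 ± 30.4 CPM (log2 fold change 2.28 ± 0.12, edgeR QL adjusted p 4.98e-08) and the cytokine IL11 by 1.21 ± 0.10. Prostate luminal and androgen response genes had 2 higher and 3 lower of 8 (4 and 3 adjusted over the list alone; camera adjusted p 0.991), with the homeobox factor HOXB13 at 187 ± 13.4 CPM without and 93.3 ± 11.9 CPM with coculture and STEAP1 at 0.74 ± 0.06.

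**Figure D3:**
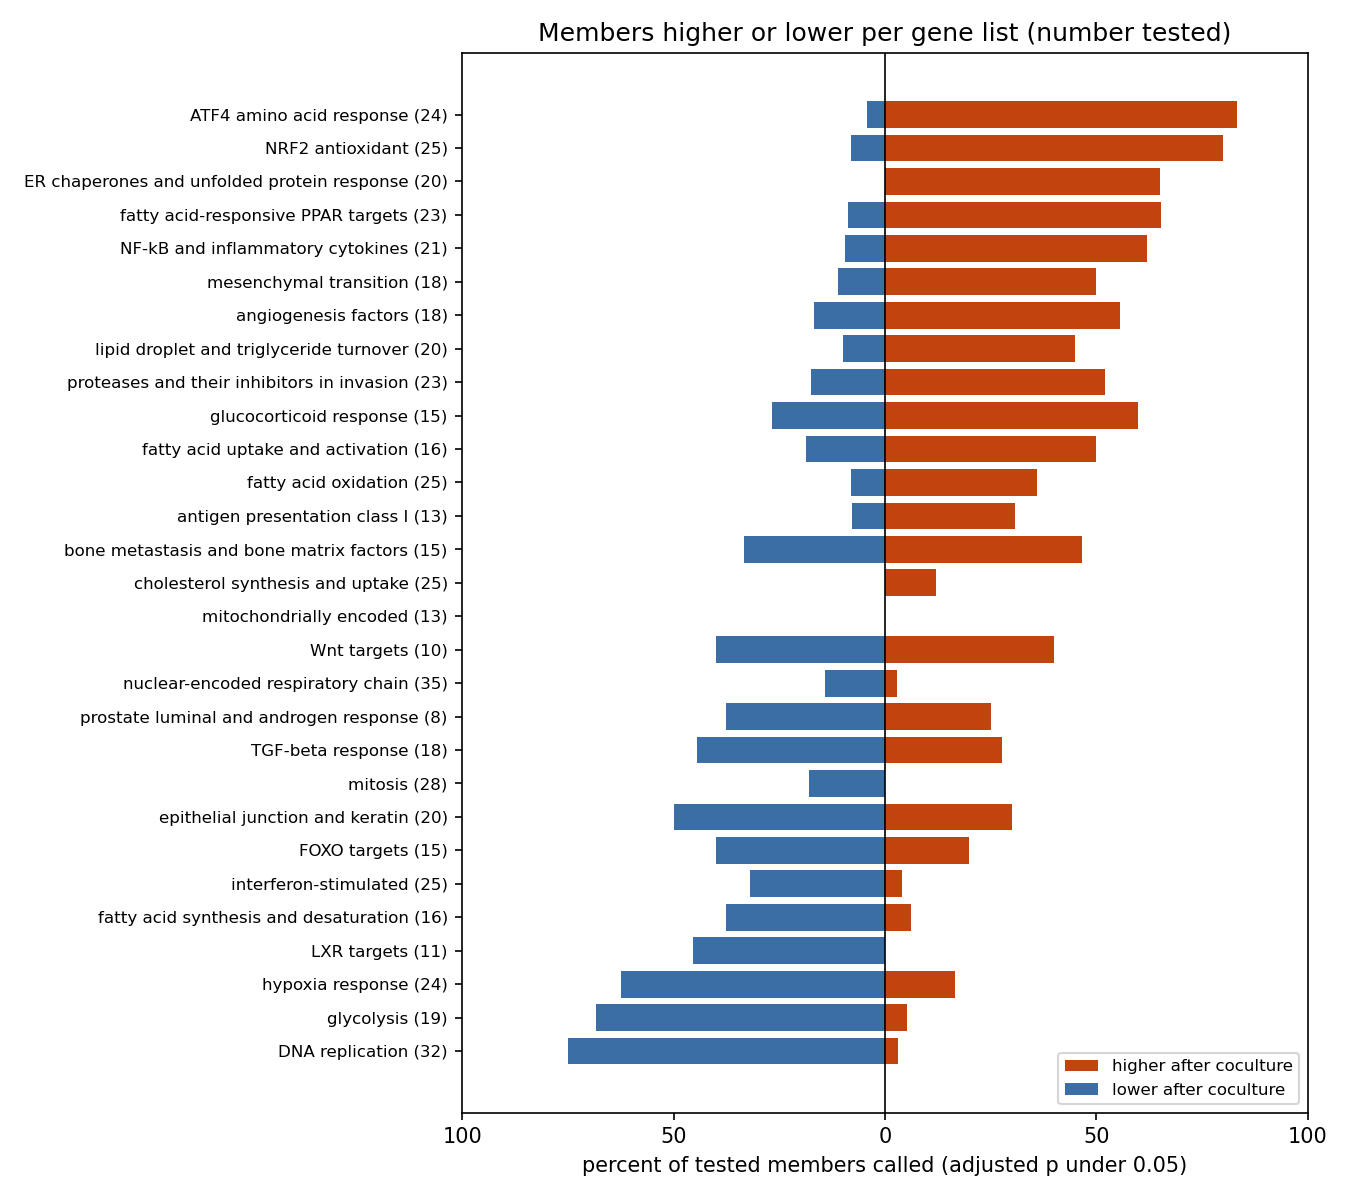
Percent of the tested members of each gene list that were higher (bars to the right) or lower (bars to the left) after coculture, at a BH adjusted p under 0.05 from edgeR QL over all genes. The ATF4 and NRF2 lists have the most higher members (20 each), and DNA replication the most lower ones (24).

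Markers of the other cells that a coculture could bring were low or moved apart. Adipocyte markers summed to 186.4 ± 11.4 CPM without and 287 ± 49.4 CPM with coculture, higher in 5 of 5 batches (exact permutation p 0.00794, equal to its BH adjusted value and the smallest it can give). The rise came from FABP4, a fatty acid-binding protein (27.1 ± 9.70 to 149 ± 50.5 CPM), and the droplet protein PLIN4 (22.6 ± 1.40 to 49.0 ± 8.09 CPM), while PPARG dropped from 125 ± 2.79 to 88.7 ± 3.38 CPM. ADIPOQ, the adipocyte hormone adiponectin, had 0 counts in the cocultivated libraries. The sum of the 10 markers under 1 CPM rose by 0.0796 CPM with an SD over batches of 0.107. That rise came from AQP7 (0.06999 ± 0.0582 to 0.2303 ± 0.08614 CPM), while PLIN1, GPD1, LPL, LGALS12 and ADIPOQ were lower. Without FABP4, the adipocyte marker share of counts fell by 17.05 CPM (exact permutation p 0.00794). As a list, the adipocyte markers had 2 higher and 2 lower of 6, over the list alone as well (camera adjusted p 0.991), and their median of -0.12 and mean of 0.33 differ in sign. The stromal, haematopoietic and endothelial sums were lower with coculture in 5 of 5 batches, at 12.19 against 16.9, 3.258 against 5.171 and 40.78 against 49.83 CPM (exact permutation p 0.00794 each, also after BH adjustment). The lower endothelial sum rests on KDR, without which it was higher, at 30.63 ± 3.615 against 25.22 ± 1.243 CPM (exact permutation p 0.0159). Without LYZ the haematopoietic sum was 2.696 ± 0.227 against 2.941 ± 0.595 CPM (exact permutation p 0.421), and without COL1A1 the stromal sum stayed lower (exact permutation p 0.00794). With the batches as pairs, an exact sign-flip permutation of the 5 differences gives 0.0625 for each of the 4 sums, the smallest p it allows.

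Among stromal markers COL6A3 was higher (1.74 ± 0.19), COL1A1 lower (-1.07 ± 0.13) and FBLN1 not called (-0.27 ± 0.10, edgeR QL adjusted p 0.0684). The list had 1 higher and 4 lower of 8 (1 and 5 adjusted over the list alone; camera adjusted p 0.0527, adjusted p 0.21 with an estimated correlation). The stromal list was called as lower with all libraries by camera on voom values (adjusted p 0.0391) and by fry (adjusted p 0.000334), and by camera without cocultivated replicate 2, 4 or 5 or non-cocultivated replicate 5 (camera adjusted p 0.0376, 0.0332, 0.0473 and 0.0443), but not with the batch as a block (camera adjusted p 0.0816, adjusted p 0.307 with an estimated correlation). FBLN1 was called as lower without non-cocultivated replicate 1, cocultivated replicate 2 or batch 2 (edgeR QL adjusted p 0.0473, 0.0228 and 0.0298) and with library totals (0.0298). Of the haematopoietic markers 3 were tested, with S100A9 higher (2.97 ± 0.39), LYZ lower (-1.95 ± 0.25) and CORO1A not called (-0.36 ± 0.14, edgeR QL adjusted p 0.0631). Over the list alone or with the batch as a block 1 was higher and 2 lower. Without coculture S100A9 was near the floor, at 0.05291 ± 0.03183 CPM, so the size of its change is uncertain. CORO1A was called as lower with the batch as a block (edgeR QL adjusted p 0.03), and without non-cocultivated replicate 1, non-cocultivated replicate 2 or batch 1 (0.0196, 0.036 and 0.0363), and with library totals (0.0271). Endothelial markers had 3 higher and 1 lower of 6, over the list alone as well (camera adjusted p 0.141), with ROBO4 at 0.43 ± 0.11, KDR at -1.23 ± 0.18 and PECAM1 at 0.13 ± 0.08 (not called, edgeR QL adjusted p 0.265, but called with the block and a length offset, 0.0333). ROBO4 was not called from TPM values (limma adjusted p 0.155).

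**Figure D4:**
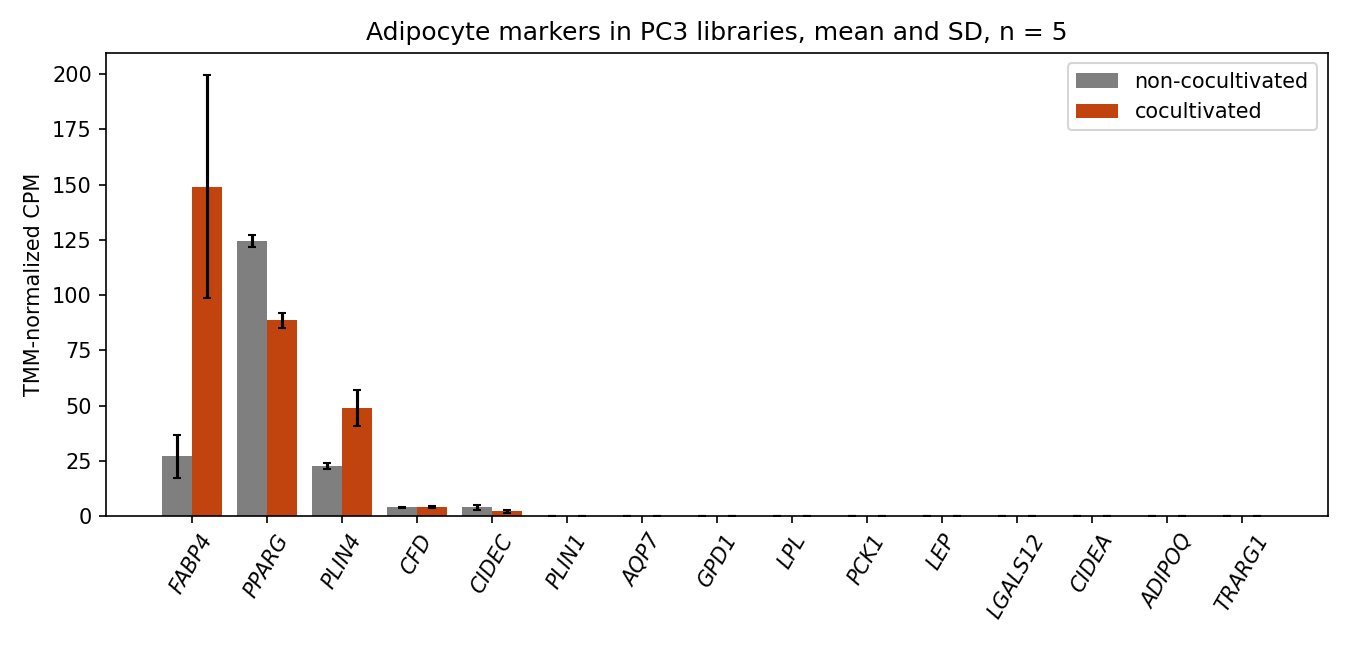
Mean level of 15 adipocyte markers in cocultivated and non-cocultivated libraries (vertical axis in CPM, bars give the mean and error bars the SD, n = 5 each). FABP4 and PLIN4 are higher with coculture, PPARG is lower, and ADIPOQ has 0 counts in the cocultivated libraries.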

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

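The tests of carry-over from adipocytes, of the counts with a GC offset, of single lists in other splits and of the counts that shared sequence can carry were chosen only after the results they address were seen.

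The change was broad, with 2801 genes higher and 2478 lower. Of 100 splits drawn from the 126 possible ones, the real split alone (1 of 100) gave as many genes higher and as many lower. The others gave at most 1 gene per direction. These splits ignore the pairing, and each mixes cocultivated and non-cocultivated libraries within its groups, which raises the spread there. They therefore cannot exclude chance for either count. The 16 splits that part all 5 batches are too few for a share under 0.05: 1 of the 16, the real split, gave as many genes in each direction, and the highest of the others called 0. With the batch as a block the counts were 3478 and 3487. With an offset for GC content added to the block they were 3524 and 3599, and with one for length 3561 and 3604. With library totals and no block they were 2216 and 3555, so none of these trends could account for the whole of the change. A response of the PC3 cells to coculture stays the open explanation, together with anything else that set the cocultivated cultures apart, such as the medium or the density of the cells, which was not tested.

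For the lists under the preset correlation, each split counts with its larger direction, because a split and its mirror are one. As many lists as the 11 higher ones were called in 1 of 100 splits, the real one, by a margin of 1 list (highest of the others 10). These splits ignore the pairing, so they cannot exclude chance for that number. The split with 10 differs from the real one by the swap of 1 batch pair, so it keeps most of the coculture contrast. Every other split keeps some of that contrast, because the 5 libraries of a group cannot be shared evenly. As many lists as the 5 lower ones were called in either direction in 51 of 100 (highest of the others 10), so chance is not excluded for them. That share, like the 10 of 16 below, is raised because the smaller direction of the real split is set against the larger one of the others. The number of 11 falls to 9 with the batch as a block, for which no splits were run, and to 0 with an estimated correlation. Among the 16 splits that part the batches, which are too few for a share under 0.05, 1 called as many lists in its larger direction as the 11 higher ones and 10 as many as the 5 lower ones (highest of the others 10). The splits in which a list had a camera p as small as the real one numbered 1 of 100 for the PPAR, ATF4, fatty acid oxidation, angiogenesis and glucocorticoid lists and 2 for the LXR, NRF2, NF-kB and mesenchymal lists. They numbered 5 for glycolysis and proteases, 6 for hypoxia, 9 for lipid droplets and ER chaperones, 13 for DNA replication and 67 for mitosis. At an adjusted p under 0.05, camera called the ATF4, NRF2, NF-kB, PPAR and LXR lists in 63, 50, 38, 27 and 16 of the 99 other splits. For the mesenchymal, glucocorticoid, fatty acid oxidation and angiogenesis lists the numbers were 9, 5, 2 and 0. Mitosis, DNA replication, ER chaperones, glycolysis, hypoxia, lipid droplets and proteases were called in 72, 57, 55, 41, 38, 24 and 4. Part of the coculture contrast remains in these splits, so none of these numbers is a rate of false calls.

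FABP4 and PLIN4, known from adipocytes, were higher in the cocultivated libraries of all 5 batches, together by 148.3 CPM. RNA of adipocytes carried into the PC3 libraries would bring the other adipocyte transcripts with it. The sum of the 10 markers under 1 CPM rose by 0.0796 CPM (SD over batches 0.107), which is 0.0537% of the rise of FABP4 and PLIN4. These markers held 111 of 219114859 counts in the cocultivated libraries. Their summed rise came from AQP7, which rose from 0.06999 to 0.2303 CPM. ADIPOQ, PLIN1, LPL, GPD1 and LGALS12 were lower, and LEP and PCK1 had 1 count each with coculture. So small a sum argues against carry-over as the source of the rise of FABP4 and PLIN4, unless the adipocytes held little of those transcripts, which was not measured here. Induction of both genes in PC3 cells may be the source, as a hypothesis found on the same libraries.

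AKR1C1, AKR1C2 and KRT83 belong to families with near-identical members. Reads of AKR1C3 counted for its paralogs would leave their ratio unchanged, but the log2 ratio of AKR1C1 plus AKR1C2 to AKR1C3 was 0.15 ± 0.403 with and -2.08 ± 0.199 without coculture, a difference of 2.2345 (exact two-sided permutation p 0.00794 unpaired, and 0.0625, the smallest possible, with the batches as pairs), which argues against that source. AKR1C2 and AKR1C1 cannot be told apart in this way, because 39.5% of the 75-base windows of AKR1C2 occur in AKR1C1. The shared windows are 21.9% of those of AKR1C1, which rose from 1.32 ± 0.298 to 34.8 ± 17.7 CPM. Its reads could thus carry a rise of about the size seen in AKR1C2, 6.97 CPM. For KRT83, 1.33% of the windows occur in KRT81 or KRT86, which lies under the bound of 10 percent set beforehand, but that bound was wrong because it left out that KRT81 held 991 CPM against 7.52 for KRT83: those windows could carry 10.2 CPM against a rise of 6.61 CPM. The log2 ratio of KRT83 to KRT81 was -7.03 ± 0.133 with and -7.07 ± 0.153 without coculture, so KRT83 cannot be told apart from reads of KRT81.

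In 16 of 182 groups of 5 values (8.79%), the highest or lowest library stood farther from the rest than Dixon's critical value of 0.71 for the gap over the range, where chance gives about 5%. Of these, 6 lay in non-cocultivated replicate 1, 5 in non-cocultivated replicate 5, 3 in cocultivated replicate 5 and 2 in cocultivated replicate 4. In non-cocultivated replicate 1, SREBF1 was at 99.33 CPM against 72.2 to 77.8 in the rest of its group (gap over range 0.794). There, MYLIP was at 14.01 against 10.92 to 11.76 (0.726), PLAU at 896.6 against 1053 to 1111 (0.729) and IFIT2 at 14.61 against 12.19 to 12.75 (0.768). KDR was at 30.32 against 21.42 to 23.87 CPM (0.725) and the endothelial sum at 58.27 against 46.29 to 49.75 CPM (0.711) in that library. In non-cocultivated replicate 5, FABP4 was at 44.41 CPM against 21.79 to 23.66 (0.917) and the adipocyte sum at 206.4 against 179.6 to 185.6 CPM (0.777). That library also held AKR1C1 at 1.846 against 1.139 to 1.239 (0.858), CYP1A1 at 7.019 against 4.144 to 4.611 (0.838) and HMOX1 at 17.64 against 12.39 to 13.35 CPM (0.818). In cocultivated replicate 5, IL1B was at 280.4 against 145.6 to 182 (0.73), GADD45A at 207.1 against 141.8 to 152.9 (0.83) and KIF20A at 47.83 against 65.15 to 69.67 CPM (0.793). In cocultivated replicate 4, SLC27A2 was at 2.351 against 1.782 to 1.905 (0.784) and ME1 at 50.22 against 45.23 to 46.35 CPM (0.776).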

How the results depend on the processing

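The fits with a GC offset, without batches 1 and 5, of the adipocyte markers without FABP4 and of the other cell type sums without their most changed marker were chosen after seeing the data. ANGPTL4 stayed called in all its alternatives, with a log2 fold change of 5.73 (TPM) to 6.54. The numbers of genes higher after coculture and of genes lower after coculture stayed within 1.5 times of 2801 and 2478 under the other fits, filters and scalings, with DESeq2 at 2831 and 2598 and limma-voom at 2786 and 2489. The exceptions follow from a stricter threshold: 358 and 283 at an absolute log2 fold change of at least 1, and 1520 lower at an adjusted p under 0.01. Leaving out a library or a batch gave 2116 to 3041 higher and 1702 to 2675 lower. With the batch as a replicate block the counts were 3478 and 3487 (2779 and 2461 of the genes shared with the fit without it), lists higher went from 11 to 9 and lists lower stayed at 5. The block ended the calls of the angiogenesis and protease lists, made CORO1A a call and, for the adipocyte marker share of counts (100.6 CPM), gave an exact sign-flip permutation p of 0.0625, the smallest 5 pairs allow. It changed no other call of a list or named gene, while the number of members called moved by more than 1.5 times in the lists where the blocked numbers are given.

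With an estimated correlation camera called 0 lists higher and 0 lower (5 and 1 at an unadjusted p under 0.05), and without members shared between lists 7 were higher, where fewer genes were tested. With fry, which compares a list with no other genes, 11 were lower, 4 of them among the 5 of camera. Over both directions, fry called 11 lists that camera had not called and lost 1. Among those gained were the Wnt, interferon-stimulated and TGF-beta lists (fry adjusted p 2.59e-06, 2.77e-05 and 0.00391). Lists higher ranged from 10 to 12 and lists lower from 5 to 6 when a library was left out. The adipocyte marker share of counts differed by 79.68 to 111.4 CPM with a library left out and by -17.05 CPM without FABP4, so its rise rests on FABP4. The endothelial cell marker share of counts turned higher without KDR, by 5.405 CPM. MT-ND4L (-0.24) and MT-ND4 (-0.28) turned negative without batches 1 and 5, never called, and the cause was not tested. At this depth, levels under 0.0768 CPM lie within the 3 counts that a count of 0 allows in the shallowest library. The stricter filter removed APCDD1 and S100A9, so it gives no value for them.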

Other observations

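The genes of the next paragraph were chosen after their values were seen, and the test of fatty acid against cholesterol synthesis, the comparisons with random lists and the mean without CDKN1A were chosen only after the result was seen. The lists of aryl hydrocarbon receptor, immediate early and p53 genes were written after the gene calls had been seen, and the exact permutation tests treat the libraries as unpaired: with the batches as pairs, a sign-flip permutation gives 0.0625 for each of the 4 differences, the smallest 5 pairs allow.

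The hair keratin KRT81 rose from 120.9 ± 20.51 to 991 ± 181.4 CPM (log2 fold change 3.04 ± 0.15, edgeR QL adjusted p 2.42e-08, n = 5 and 5), and its close paralog KRT86 rose by 2.91 ± 0.15, though 33% of the 75-base windows of KRT81 also occur in KRT86. The morphogen SHH rose from 14.63 ± 4.083 to 70.13 ± 11.35 CPM (2.26 ± 0.16), the anticoagulant receptor THBD from 2.68 ± 0.349 to 16.05 ± 2.853 CPM (2.59 ± 0.13) and the secreted protein CCDC80 from 11.43 ± 1.036 to 72.14 ± 6.058 CPM (2.66 ± 0.07). Each of these genes was higher in 5 of 5 batches.

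SREBF1 fell while no cholesterol gene was called lower in the fit without the batch (3 were with it), which led to the hypothesis that the fatty acid branch of lipid synthesis was lowered apart from the sterol branch. The mean log2 CPM of the fatty acid synthesis list minus that of the cholesterol list was lower by 0.26 with coculture (-0.2623, SD of the batch differences 0.1277), lower in 5 of 5 batches, with an exact two-sided permutation p of 0.00794, the smallest it can give. This does not test the hypothesis, because the list holds SREBF1 and the calls that prompted it. Without SREBF1 the difference was -0.1903 (SD of the batch differences 0.1315), lower in 4 of 5 batches, and camera called neither list.

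The decrease of CYP1A1 led to the hypothesis of lower activity of the aryl hydrocarbon receptor, the sensor that induces it. The mean log2 CPM of its 7 other tested targets differed by -0.3645 (lower in 5 of 5 batches; exact two-sided permutation p 0.0159, BH adjusted over 3 such lists 0.0159). CYP1B1 (-1.70), AHRR (-1.56), TIPARP (-0.52) and ALDH3A1 (-0.43) fell and TGM2 rose (1.71). Camera did not call the list (adjusted p 0.0674, and 0.253 with an estimated correlation), while 1.43% of 10000 random lists of its size were as low, so lower receptor activity may be a candidate explanation for part of these genes, with TGM2 against it.

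The increase of EGR1 led to the hypothesis that immediate early genes rose together. The other 20 had a mean higher by 0.2826 in log2 CPM (5 of 5 batches; exact two-sided permutation p 0.00794, BH adjusted 0.0119), with 11 members higher and 0 lower. Camera called them (adjusted p 0.00172, but 0.23 with an estimated correlation) and 0.88% of random lists were as high, which is consistent with the hypothesis. FOS (-0.34 ± 0.28, edgeR QL adjusted p 0.38) and FOSB (-0.29 ± 0.18, 0.248) were not called.

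PHLDA3 is a target of p53, which PC3 cells are known to lack, so the same was asked of 20 other p53 targets. Their mean was higher by 0.1348 (5 of 5 batches; exact two-sided permutation p 0.00794, BH adjusted 0.0119), and 0.0652 without CDKN1A. Of these 8 were higher and 2 lower, with CDKN1A at 1.49 and MDM2, a main target, at -0.15. Camera did not call the list (adjusted p 0.129, and 0.23 with an estimated correlation), and 7% of random lists were as high, so a joint rise of p53 targets is at most weak here and PHLDA3 may rise in another way.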
